A study of Mus musculus with 69 samples.

How the data were processed

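The series holds 69 libraries, each made from a single cell of miR-146a-/- C57BL6/J mice. miR-146a is a microRNA that dampens inflammatory signalling through NF-kB. The cells were ESLAM cells, a bone marrow fraction enriched for haematopoietic stem cells and sorted as EPCR+ CD45+ CD150+ CD48-. They came from pooled mice of 10 to 14 weeks, per the labels. All 69 libraries form 1 group and stem from 1 pool, so cells were not treated as replicates of an animal. The SD given with a mean over cells is the spread between cells, and no group was compared with another. Wild type cells named in the design text belong to another series and were not analysed here. The design text counts 43 cells as passing quality control, and the labels do not say which. Cells are called by their number in the order of deposition, a name with no further meaning.

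Post-bisulfite adapter ligation was used, per the labels' protocols: lysed cells were treated with bisulfite, which converts unmethylated cytosine, and adapters were ligated afterwards. T7 phage DNA was added before conversion, per the labels' protocols, and its conversion rate was not used here. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.2, Trim Galore 0.4.0, cutadapt 1.2.1, Novoalign, SAMtools 0.1.17, Picard 1.31 and bedtools, without role or order. They name the builds mm8, GRCm38 and mm10. The filters on reads and the handling of duplicates are not given in the sources used here. The highest positions on chromosomes X and Y fit the lengths of GRCm38, and all coordinates are of that build and 1-based.

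Each deposited file lists CpG sites with at least 1 call. The deposited percent is the methylated share of the calls at a site and matched the ratio of the deposited counts at every site, within a small tolerance. The deposited counts are methylated calls and all calls per site, not normalized, with both strands merged into 1 record. The seventh column of the deposited files holds 1 or 2 per site, its meaning is not stated, and no main result uses it. Calls are not independent molecules, because no molecular identifiers were used and a fragment may be called more than once. All intervals therefore cover counting error only.

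Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, scikit-learn 1.9.0 and matplotlib 3.10.9 was used. Libraries with at least 200000 covered sites entered the main results. The level of a library is its methylated calls over all its calls, with a 95% Wilson interval. CpG density is the number of sites, seen in any library, within 500 bp of a site, the site itself included. A standardised level weights the levels of 6 density classes by the share of each class among all sites seen in any library.

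The annotation at hand was a RefSeq table of GRCm38.p6 with the start and end of each gene but without strand, exons or sequence. The planned promoters, exons, introns and repeats could therefore not be drawn. A window of 1000 bp outside and 500 bp inside was placed on each end of a gene of at least 1000 bp. The end with at least 1.5 times the CpG sites of the other end, and at least 10 sites, took the place of the promoter and is called the denser gene end. Whether it is the start or the end of transcription is unknown for any gene. Windows with at least 60 sites are called CpG-rich and those with fewer than 30 CpG-poor. Gene bodies are the remaining sequence of protein coding genes, and intergenic sequence lies in no annotated gene or gene end.

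A gene end was measured when at least 10 cells and at least 5 sites had calls. Its level pools the calls of all cells. It was classed as unmethylated under 20%, intermediate from 20% to 80% and methylated above 80%. The 16 gene lists were fixed before the data were examined. The median of a list was placed among 10000 random lists of the same size, matched on the number of CpG sites by deciles. That percentile describes these libraries and is not a p-value. A gene end was called discordant where, among at least 10 cells with at least 3 covered sites, at least 20% of cells stood at 80% or more and at least 20% at 20% or less. Dissimilarity of a pair of cells is the mean absolute difference of the site levels over the sites covered in both. Both measures were set beside 20 shuffles, which exchanged the calls of a site between the cells covering it.

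Depth and level were related across libraries by Pearson's r and Spearman's rho with 2-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment over 5 relations. These p-values describe the libraries of 1 pool, not mice. All libraries carry the same flow cell and lane in their labels, so no batch could be examined. The named genes were chosen by a rule fixed before the data were examined. It takes the 2 highest and 2 lowest members of each list, the imprinted list in full where summarised, the 10 discordant gene ends with the highest smaller share of cells, and Mir146 with its host gene, for which the table has no entry. Not every gene that the rule takes is described. Other genes are named as chosen after their values were seen. Alternatives covered the cell filter, the calls per site, autosomes alone, weighting, the window, the class limits and the filters on gene ends. Alternatives added after seeing the data left out libraries of uneven chromosome coverage or rich in CpG-dense sites, or changed the rule for the denser end. Simulated calls on the coverage of the 46 libraries tested the procedure. Of 200 gene ends simulated as discordant, 98.5% were called. A further 200 were simulated as methylated and the remaining ones as unmethylated, none at intermediate levels, so the simulation gives no rate of false calls. The shuffles of the deposited calls give a count to set beside the observed one, but no such rate either. They cannot move calls at a site covered by 1 cell.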

Results

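The data are CpG methylation calls of 69 single miR-146a-/- ESLAM cells from the bone marrow of pooled mice. ESLAM cells are a sorted fraction rich in haematopoietic stem cells, and miR-146a is a microRNA that restrains NF-kB signalling. The study as titled links inflammation through IL6 and TNF with myeloid malignancy. The files describe 1 genotype, so the question they answer is what the methylome of these cells looked like and how far cells differed from each other. Of the 69 libraries, 46 had at least 200000 covered sites and were used. The other 23 held 371 to 198719 sites. The design text counts 43 cells as passing, by a rule that is not given. The libraries used covered 576069 sites on average (range 231282 to 1481922) with 373765 to 2500890 calls. A covered site had calls in 1.94 cells on average, so that gene levels below rest on pooled calls of 10 or more cells.

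The genome of these cells was highly methylated outside CpG-dense sequence. The level was 74.5% ± 3.03 (SD, n = 46 cells), from 66.5% to 78.0%. Sites with fewer than 5 CpG sites within 500 bp stood at 91.1% ± 0.65 (SD, n = 46), and those with 60 or more at 4.79% ± 0.918 (SD, n = 46). Standardised to a common CpG density, the level was 80.9% ± 0.595 (SD, n = 46). The 95% Wilson intervals of single libraries were at most 0.299 percentage points wide.

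The lower raw levels belonged mostly to cells with more of their sites in CpG-dense windows (40 or more sites within 500 bp). This share ran from 10.7% to 20.4%. Sites in such windows stood at 14.9% (40 to 59 sites) and 4.79% (60 or more), so a larger share lowers the raw level by arithmetic. A fall is thus built in, and the p-values of that relation, over all libraries and on each side of 15%, are no evidence beyond it. Whether the arithmetic accounts for the whole fall was not tested. The level also weights sites by their calls, and what sites of many calls add to its spread was not tested. Cells 1 and 10 stood at 69.6% and 68.5%, each with 14.0% of sites in CpG-dense windows. Cell 7 stood higher, at 72.1%, with a share of 15.3%. Across the 46 libraries the level fell as this share rose (r = -0.915, permutation p = 1e-05, adjusted 1.67e-05, the smallest p that the permutations allow; rho = -0.908, permutation p = 1e-05, adjusted 2.5e-05). Without the 2 libraries farthest from the median share, r was -0.891. These p-values describe libraries of 1 pool, not mice. Because 8 libraries had a share above 15%, the relation was computed on each side, a family of 2 relations. It was r = -0.843 in the 38 libraries at or under 15% (permutation p = 2e-05, adjusted 4e-05; rho = -0.845, permutation p = 2e-05, adjusted 4e-05; r = -0.760 without the 2 farthest) and r = -0.915 in the 8 above (exact permutation p = 0.00139, adjusted 0.00139; rho = -0.857, exact permutation p = 0.0107, adjusted 0.0107; r = -0.841 without the 2 farthest). The standardised level still fell with the share (r = -0.658, permutation p = 1e-05, adjusted 1.67e-05; rho = -0.579, permutation p = 3e-05, adjusted 5e-05), with r = -0.608 without those 2 libraries. Depth, as log10 of the covered sites, showed no detectable relation to the level (r = 0.135, permutation p = 0.375, adjusted 0.375; rho = 0.168, permutation p = 0.266, adjusted 0.266; r = 0.155 without the 2 libraries of most extreme depth). Including libraries from 50000 sites on, r was 0.433, and without the libraries rich in CpG-dense sites it was 0.382, both past the 0.05 threshold. From 500000 sites on it was -0.285, not past it.

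**Figure D1:**
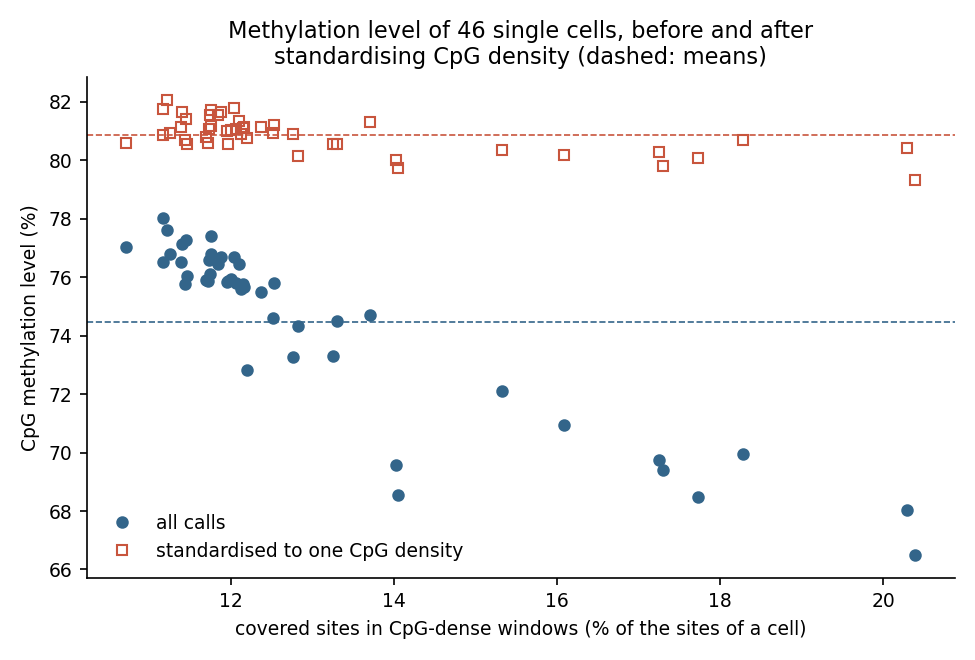
Methylation level in percent (vertical) against the share of covered sites in CpG-dense windows in percent (horizontal) for 46 cells, with filled circles for all calls and open squares for levels standardised to a common CpG density; dashed lines are means. Raw levels run from 66.5% to 78.0% and fall with the share, and the standardised levels lie around 80.9%.

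Gene bodies were methylated and CpG-rich gene ends were not, in every cell used. CpG-rich denser gene ends, a class that resembles CpG islands, stood at 4.88% ± 1.15 (SD, n = 46) and gene bodies at 77.6% ± 2.48 (SD, n = 46). The difference within a cell was 72.7 percentage points ± 1.80 (SD, n = 46), above 0 in 46 of 46 cells. CpG-poor gene ends stood at 61.3% ± 2.29 (SD, n = 46) and intergenic sequence at 85.5% ± 1.49 (SD, n = 46). Gene bodies minus intergenic sequence gave -7.88 percentage points ± 1.15 (SD, n = 46), below 0 in all 46 cells. At a common CpG density the sign turned, to 0.539 ± 0.456 (SD, n = 46), above 0 in 42 cells.

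Chromosome X stood at 79.5% ± 2.68 (SD, n = 46) and the autosomes at 74.4% ± 3.05 (SD, n = 46), a difference of 5.12 percentage points ± 2.38 (SD, n = 46) that was above 0 in 46 cells. At a common CpG density X was lower instead, by -2.87 percentage points ± 1.19 (SD, n = 46), in 46 cells. Chromosome 17 had the lowest raw level, 65.1% ± 5.99 (SD, n = 46), and chromosome 16 the widest spread, 71.4% ± 7.80 (SD, n = 46). With sites of more than 4 calls left out these became 74.3% ± 2.70 (SD, n = 46) and 77.9% ± 2.95 (SD, n = 46). A window on chromosome 17 from 39840000 to 39849999, at the ribosomal RNA gene Rn18s-rs5, alone held 0.727% of all calls at a level of 13.9%. On chromosome 16, windows at 11140000 to 11149999 (Zc3h7a) and 57390000 to 57399999 (Cmss1 and Filip1l) held 0.117% and 0.118%, at 5.50% and 7.19%.

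**Figure D2:**
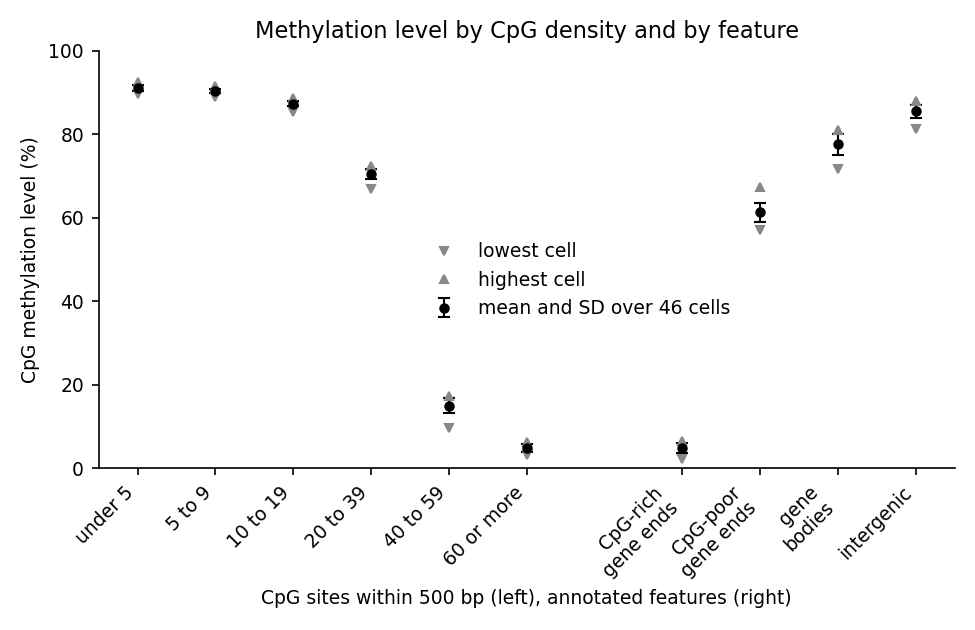
CpG methylation level in percent (vertical) by number of CpG sites within 500 bp and by annotated feature (horizontal) in 46 cells; circles with bars are means and SD over cells, and triangles the lowest and highest cell. The level falls from 91.1% at under 5 sites to 4.79% at 60 or more.

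The locus that the genotype removes gave no calls. Mir146, the microRNA gene on chromosome 11 from 43374397 to 43374461 (GRCm38), had 0 calls over all 69 libraries, and so did the 565 bp that surround and include it. The flanks of 50 kb held 754 calls at 267 sites on the lower-coordinate side and 1070 calls at 399 sites on the higher one. No host gene is annotated there in the table used. No genome sequence was at hand to show whether the 65 bp hold any CpG, and sites in the flanks lay at only 5.34 and 7.98 per kb. The 0 calls therefore do not check the genotype.

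Across named genes, housekeeping, stem cell, leukaemia and inflammatory genes had mostly unmethylated denser ends, as did the measured genes as a whole. The same held for neuronal, Hox and DNA methylation machinery genes. Germline genes were mostly methylated and imprinted genes mostly intermediate. Of 21888 genes considered, 14924 had a denser end and 12124 of these were measured, with a median of 280 calls from 14 cells. Of the measured ends, 9695 (80.0%) were unmethylated, 1219 (10.1%) intermediate and 1210 (9.98%) methylated. Among 6569 CpG-rich ends, 98.3% were unmethylated, 98 intermediate and 12 methylated. Among 1749 CpG-poor ends, 14.1% were unmethylated and 54.3% methylated. In 4679 genes with both ends measured, the median was 5.39% at the denser end and 92.1% at the other, and the denser end was lower in 93.1% of them. When cell levels were averaged in place of pooled calls, 62.8% of ends were unmethylated and 3297 were intermediate.

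Stem cell identity genes were unmethylated in 16 of 19 measured members (median 3.05%, percentile 13.7 of matched random lists). Meis1, a homeobox partner of HOX proteins in stem cells, stood at 0.476% (95% Wilson interval 0.0841% to 2.65%, 210 calls, 10 cells) in the window on chromosome 11 from 19019152 to 19020651, at its higher-coordinate end. Lyl1, a haematopoietic transcription factor, stood at 0.85%. Erg, an ETS family transcription factor gene, stood at 95.1% (162 calls) in the window at its lower-coordinate end. Of 17 measured genes mutated or rearranged in myeloid malignancy, 16 were unmethylated (median 3.19%, percentile 25). Tet2, a DNA demethylase gene, had 0% in 240 calls from 10 cells, with a Wilson upper bound of 1.58%, and Gata2 stood at 1.62%. The exception was Dnmt3a at 97.4% in 38 calls, in a window with 14 sites, and Runx1 was the next highest at 15.5%.

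Genes of IL6, TNF and NF-kB signalling were unmethylated in 13 of 15 measured members (median 5.84%, percentile 66.8). Rela and Rel, which encode NF-kB subunits, stood at 1.11% (809 calls) and 1.30% (386 calls). The window of Rela spans 5636442 to 5637941 on chromosome 19. Tnf stood at 46.7% (interval 36.9% to 56.9%, 92 calls, 16 cells) and Nfkb2 at 91.8% (170 calls), the latter at its higher-coordinate end. All 7 measured members of the list of miR-146a targets were unmethylated (median 5.84%, percentile 95.6), among them Numb at 1.46%, Smad4 at 2.86% and Notch1 at 6.79%. The DNA methylation machinery was unmethylated in 8 of 10 members (median 9.06%, percentile 86.2). Tet2 and Mbd4 (2.59%) were lowest, and Dnmt1 (100% of 128 calls, window at its lower-coordinate end) and Dnmt3a (window at its higher-coordinate end) highest. Without strand, the windows of Erg, Nfkb2, Dnmt1 and Dnmt3a may lie where transcription ends. Their high levels cannot be read as those of promoters.

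Lineage genes were mixed. In the myeloid list 4 of 9 measured members were unmethylated and 3 methylated, with a median of 48.7% (percentile 99.9). That median is the value of Prtn3, named here after its value was seen, whose window lies at its higher-coordinate end. Without strand, the median and percentile cannot be read as those of myeloid promoters. Gfi1 (1.30%) and Cebpa (2.40%), transcription factors of early myeloid cells, were lowest. Ngp, a neutrophil granule gene, stood at 92.9% (42 calls), and Spi1, which encodes PU.1, at 96.0% at its higher-coordinate end. The window of Spi1 may lie where transcription ends, so its high level cannot be read as that of a promoter. Erythroid and megakaryocyte genes were unmethylated in 5 of 8 (median 6.33%, percentile 8.82), from Tfrc (1.98%) and Zfpm1 (2.67%) to Itga2b (62.8%) and Gp9 (80.3%). Lymphoid genes were unmethylated in 4 of 8 and methylated in 3 (median 25.3%, percentile 73.8). Bcl11b stood at 1.60%, and the B cell genes Cd79a at 98.9% and Igll1 at 100% of 52 calls. Cd4 stood at 4.81% in pooled calls at its lower-coordinate end, but its mean over cells was 22.9% ± 39.1 (SD, n = 12 cells). The medians of these short lists changed with the processing. They ran from 2.40% to 63.6% for the myeloid list, from 2.67% to 24% for the erythroid and megakaryocyte list and from 3.88% to 59.6% for the lymphoid list. The lowest myeloid and erythroid and megakaryocyte medians rest on 3 CpG-rich members each.

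Germline genes, which are silent in somatic cells, were methylated in 13 of 16 measured members (median 94.0%, percentile 100). Rpl10l, a testis ribosomal protein gene, stood at 99.2% (245 calls) and Dazl at 97.9% (235 calls, chromosome 17 from 50293121 to 50294620). Ddx25 (3.20%) and Tdrd1 (58.2%) were lowest. With CpG-rich ends alone only Dazl and Ddx25 were left, and their median of 50.5% lies between opposite levels. Pluripotency genes were split, with 2 unmethylated, 3 intermediate and 2 methylated (median 43.3%, percentile 81.1). Sox2 (2.84%) and Fgf4 (8.19%) were lowest and Dppa5a (96.7%) and Tcl1 (96.8%) highest. Housekeeping genes were unmethylated in 14 of 15 (median 3.90%, percentile 33.5), with Snrpd3 at 0.246% and Polr2a at 2.05%. Chmp2a stood at 19.2%, and Actb at 66.1% in a window of 11 sites.

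Hox genes were unmethylated in 25 of 27 (median 6.36%, percentile 82.9), from Hoxb9 (1.43%) and Hoxd13 (1.78%) to Hoxc6 (45.7%) and Hoxa3 (81.9%). Neuronal genes were unmethylated in 8 of 9 (median 3.81%, percentile 1.72), with Snap25 at 0% of 73 calls (Wilson upper bound 5.00%), Syn1 at 1.42%, Dlx1 at 12.9% and Rbfox3 at 94.6%. The windows of Hoxa3 and Rbfox3 lie at their lower-coordinate ends. Without strand, their high levels cannot be read as those of promoters. Endothelial and stromal genes were unmethylated in 4 of 7 and intermediate in 3 (median 11.6%, percentile 26.7). Esam (0.680%) and Cxcl12 (5.06%) were lowest and Tie1 (48.6%) and Cdh5 (77.7%) highest. Of 5 liver genes 3 were intermediate (median 63.9%, percentile 60.7), with Apoa1 at 8.50%, Apoa2 at 23.9%, Ttr at 75.0% and Afp at 100% of 45 calls. The median ran from 5.52% to 45.7% over alternatives for pluripotency genes, the lowest with 2 members left, from 3.91% to 32.7% for endothelial and stromal genes, from 6.95% to 70.4% for liver genes and from 1.68% to 12% for neuronal genes.

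**Figure D3:**
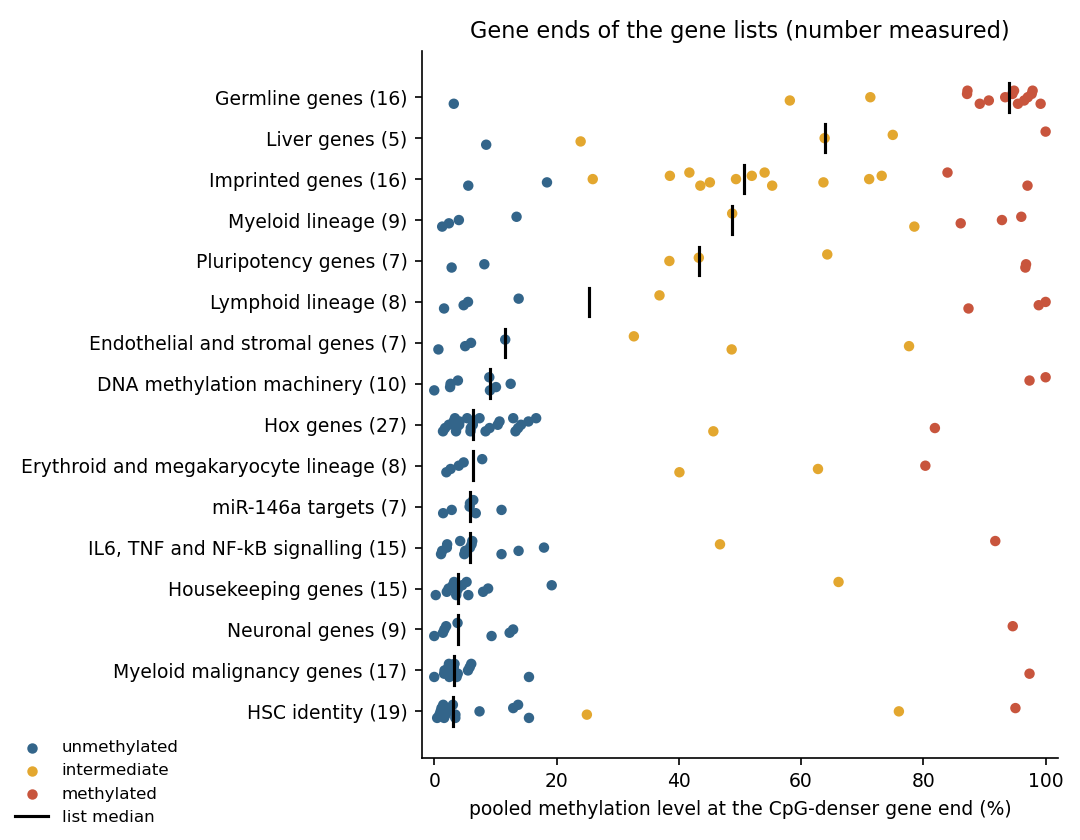
Pooled methylation level in percent at the CpG-denser end (horizontal) of each measured gene of 16 lists (vertical, number measured in brackets); points are genes coloured by class and black bars are list medians. Germline genes gather near 94.0%, imprinted genes spread around 50.6%, and most stem cell and myeloid malignancy genes lie near 0.

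Imprinted genes, which carry methylation on the allele of 1 parent, stood at intermediate levels in 12 of 16 measured members (median 50.6%, percentile 100). The intermediate members ran from Igf2r (25.9%) and Magel2 (38.5%) through Nap1l5 (41.7%), H19 (43.5%), Sgce (45.1%), Kcnq1ot1 (49.4%), Zrsr1 (51.9%), Peg3 (54.0%), Peg13 (55.3%), Plagl1 (63.7%) and Peg10 (71.1%) to Gnas (73.2%). Grb10 (5.56%) and Inpp5f (18.4%) were lower, and Mest (84.0%) and Zdbf2 (97.0%) higher. Of 13 imprinted genes with enough cells, 9 were discordant between single cells, and 2 of these were discordant in none of the 20 shuffles. Peg13 was discordant in 15 shuffles, Sgce in 9, Inpp5f in 8 and Kcnq1ot1 in 1. The count of 9 alone therefore does not show alleles that differ. At Kcnq1ot1, chromosome 7 from 143296048 to 143297547, 46.2% of 13 cells stood at 80% or more and 46.2% at 20% or less.

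Over all genes, 427 of 9340 gene ends (4.57%) were discordant between cells, including 136 CpG-rich ends. Shuffling the calls of each site between cells gave 376.8 ± 9.41 (SD, 20 shuffles; 364 to 399), so the observed count lay above all 20 shuffles, by less than the count that shuffling itself gave. The shuffle leaves in place the 24.2% of covered sites of a cell that no other cell covers. Where cells cover different sites of a window, differences between sites can pass as differences between cells and outlast the shuffle. The shuffled count is therefore no rate of false calls. The 10 discordant ends with the highest smaller share of cells were those of Mrpl42, Mucl3, Peg13, Kcnq1ot1, Rad51c, Sgce, Cdk8, Fbxw5, Armc5 and Adamts16. Peg13, Kcnq1ot1 and Sgce are imprinted. Mrpl42, Mucl3, Rad51c, Cdk8, Fbxw5 and Armc5 were discordant in all 20 shuffles too, Adamts16 in 18, Peg13 in 15, Sgce in 9 and Kcnq1ot1 in 1. The count depended on the filter and was 85 with sites of at least 2 calls.

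Any pair of cells differed by 12.9 percentage points per shared site on average (SD 0.831 over 1035 pairs, range 10.3 to 15.9), at a median of 18056 shared sites. The difference was 5.45 percentage points at CpG-rich gene ends, 12.3 in gene bodies, 15.6 at CpG-poor gene ends (785 pairs) and 15.7 in intergenic sequence. At levels near 0 the measure can hardly be large, and it was not shuffled by feature, so these values do not rank how alike cells were. Shuffled calls gave a mean of 12.86, which the shuffle keeps near the observed one by construction, and a smaller SD, 0.596. The observed SD was 1.39 times the shuffled one. A site covered in only 2 cells keeps its difference under the shuffle. The 8 libraries with over 15% of sites in CpG-dense windows had the lowest mean dissimilarities, 11.9 to 12.4. All 8 lay below their shuffled means, as did some other cells. The wider SD therefore cannot be read as structure between cells apart from the make-up of the libraries. Clustering on the excess over the shuffles split off 2 of the 46 cells, with a silhouette of 0.218. No silhouette of shuffled calls was computed, so whether the cells form separate populations was not tested. Pairs share cells, so no test was made over pairs. Mean dissimilarity fell with depth (r = -0.625, permutation p = 1e-05, adjusted 1.67e-05; rho = -0.645, permutation p = 1e-05, adjusted 2.5e-05; r = -0.607 without the 2 libraries of most extreme depth). In the 23 libraries with at least 500000 sites the relation was past no threshold (r = -0.398, permutation p = 0.0599). Its excess over the shuffles fell with depth as well (r = -0.434, permutation p = 0.00295, adjusted 0.00369; rho = -0.450, permutation p = 0.00174, adjusted 0.00218; r = -0.412 without those 2 libraries).

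**Figure D4:**
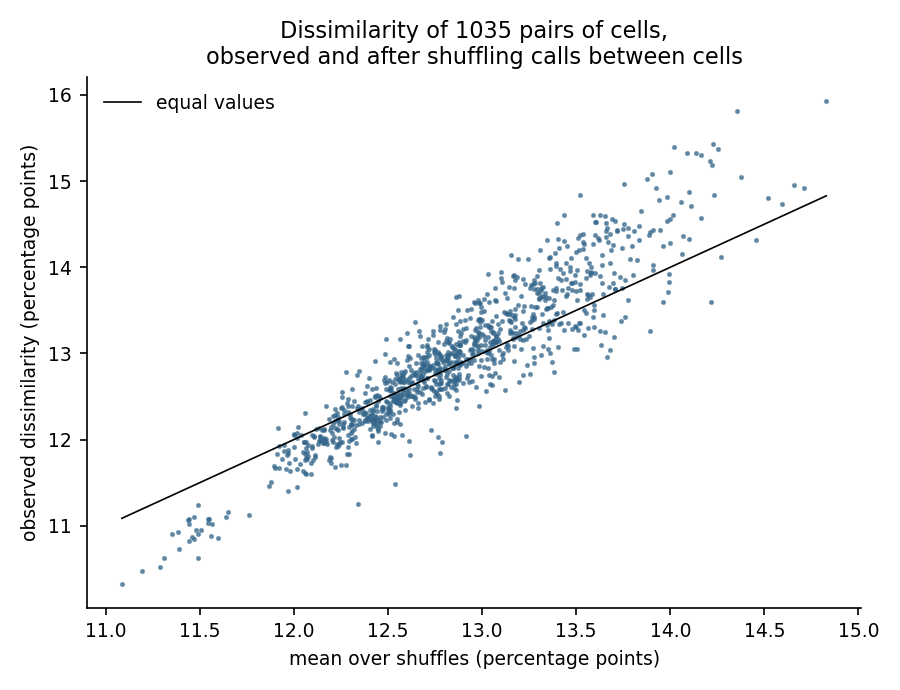
Observed dissimilarity in percentage points (vertical) against its mean over 20 shuffles in percentage points (horizontal) for 1035 pairs of 46 cells, with a line at equal values. Observed values span 10.3 to 15.9, and pairs with high shuffled values mostly lie above the line.

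Coverage was called uneven in 3 of the cells used, those with an autosome under 0.6 of the coverage of the median cell. The next lowest was cell 39, at 0.761 on chromosome 19. Relative to the median cell, cell 45 had 0.455 of the coverage of chromosome 6, cell 52 had 0.543 of chromosome 11 and cell 53 had 0.497 of chromosome 1. Bins of 10 Mb along these chromosomes ran from 0.160 to 0.772 in cell 45, from 0.321 to 0.913 in cell 52 and from 0.174 to 0.957 in cell 53. Without these cells the level was 74.4% ± 3.10 (SD, n = 43).

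**Figure D5:**
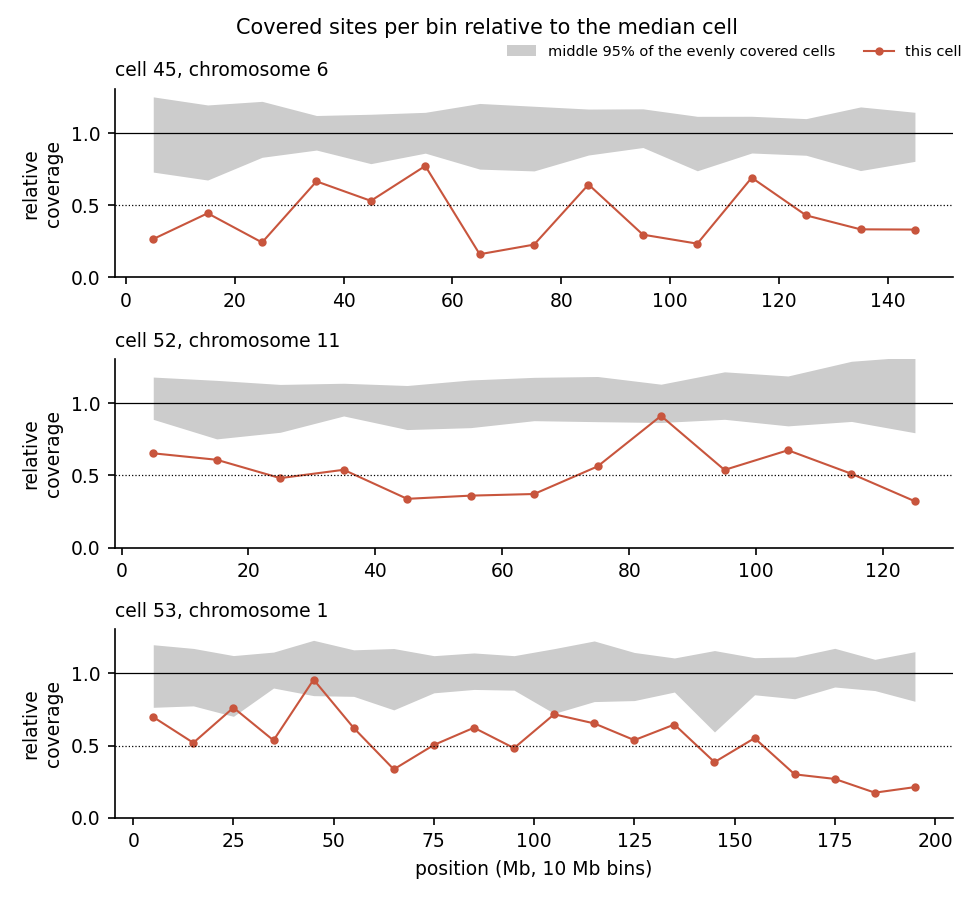
Coverage relative to the median cell (vertical, a ratio) in 10 Mb bins by position in Mb (horizontal) for cell 45 on chromosome 6, cell 52 on chromosome 11 and cell 53 on chromosome 1; grey bands hold the middle 95% of the 43 evenly covered cells, and lines mark ratios of 1 and 0.5. The 3 cells vary from bin to bin, cell 45 between 0.160 and 0.772.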

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

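All tests in this part were chosen after the result was seen, except the test of incomplete conversion.

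The seventh column, which the main results do not use, held a signal of its own: among sites with 2 to 8 calls, 10.08% of those where it is 2 were at an intermediate level (334202 sites), against 0.460% where it is 1. Incomplete conversion of unmethylated sites as the whole source is argued against by a share of 9.782% (interval 9.42% to 10.2%) in windows with fewer than 5 sites, above the 7.67% (7.46% to 7.89%) in those with 60 or more, but a contribution stays open because it was 12.4% (12.1% to 12.7%) with 20 to 39 sites and 10.6% (10.2% to 11%) with 40 to 59. A difference between alleles would lower the share on chromosome X in the 43 cells with more than 0.05% of sites on Y, but it was 10.22% there (interval 9.11% to 11.5%) and 10.2% on autosomes. The column may count strands, which stays open, since sites at 2 were 0.5148 times as frequent on X as on autosomes (bootstrap interval 0.480 to 0.554). Methylation that differs between strands was not tested as a biological explanation, as no group bears on it.

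The 23 libraries left out for shallow coverage also carried methylation signal. Their levels had a median of 69.9% and ran from 52.5% to 79.1%, on as few as 567 calls and with Wilson intervals up to 8.06 percentage points wide. Standardised to a common CpG density they had a mean of 76.3% ± 5.65 (SD, n = 23; median 79.6%) and ran from 64.3% to 82.1%, against 79.3% to 82.1% in the libraries used. The lowest, library 14, rests on 102741 calls.

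The spread of the level between cells, 3.03 percentage points, was weighed against coverage. Depth as the main source is argued against by r = 0.1346 (bootstrap interval -0.188 to 0.423), short of the 0.7 set as the bound. The CpG density of the covered sites remains a candidate explanation, because the SD fell to 0.5952 percentage points, 19.7% of the raw SD, once density was standardised. Standardising fixes the weight of each density class whatever its number of calls. The drop therefore cannot tell the density of covered sites from many calls at single sites. Why some libraries hold more CpG-dense sites was not tested, and no biological explanation was tested because there is 1 group.

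Cells 45, 52 and 53 had low coverage of single autosomes. Loss of 1 whole chromosome copy alone would leave even coverage along it, but the coefficient of variation over bins was at least 0.3124, above every one of the 43 evenly covered cells, whose highest was 0.215. Patchy recovery of the DNA may account for it, since the other autosomes were uneven as well, with a median coefficient of at least 0.1532 against 0.0779 to 0.0785 in the median evenly covered cell, though 4 evenly covered cells exceeded cell 45 and 1 exceeded cell 53 in this. In the same cells other autosomes reached 1.25, 1.51 and 1.26 times the coverage of the median cell, and X held 0.810%, 2.69% and 0.720% of sites, against a median of 1.68% in the 43 cells with more than 0.05% of sites on Y. Loss of parts of chromosomes, or of a copy on top of patchy recovery, was not tested.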

How the results depend on the processing

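A covered site had calls in 1.94 cells on average, so gene levels are limited to pooled calls. No paired comparison of groups was possible because there is 1 group, while features were compared within each cell. The level (72.9% to 76.3% over 9 alternatives), gene bodies minus CpG-rich ends (71.7 to 73.6) and the standardised difference of X and autosomes (-3.05 to -2.79) kept their direction and moved by less than the SD. No result past its threshold reversed. Of 358 alternative values for the main results, 315 stayed within the limits set. The cause of the changes below was not tested, apart from fewer libraries, sites or gene ends entering.

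From 50000 sites on, 54 libraries passed, dissimilarity was 13.98 and depth against level r = 0.433. From 500000 sites on, 23 libraries passed, with 5496 unmethylated, 585 intermediate and 445 methylated gene ends, 183 discordant, and depth against dissimilarity r = -0.398. Sites of at least 2 calls gave 656 intermediate and 479 methylated ends, 85 discordant (73.2 shuffled) and a myeloid median of 12.8%. Windows of 500 bp on each side gave 574 intermediate and 723 methylated ends, 105 discordant (80.0 shuffled), medians of 12.3% for myeloid and 6.95% for liver genes, and 64.0 points for CpG-poor minus CpG-rich ends (56.4 in the main result). The looser filter gave 2001 methylated ends. Limits of 10% and 90% gave 3011 intermediate and 270 discordant ends, and 5 sites per cell 118 discordant (83.8 shuffled). Averaging cells gave 3297 intermediate ends and a housekeeping median of 10.8%.

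The following alternatives were added after seeing the data. Without libraries of uneven coverage no main result moved. Without libraries rich in CpG-dense sites there were 758 methylated and 255 discordant ends (242.8 shuffled), medians of 14.0% for myeloid and 16.8% for liver genes, and depth against level r = 0.382. A gene end at least 3 times denser gave 578 intermediate, 426 methylated and 265 discordant ends, a myeloid median of 13.5%, and 48.1 points for CpG-poor minus CpG-rich ends. A denser end by any margin gave 1887 methylated ends and 60.4 points. CpG-rich ends alone gave 6459 unmethylated, 98 intermediate, 12 methylated and 136 discordant ends, with medians of 2.40% for 3 myeloid, 50.5% for 2 germline and 5.52% for 2 pluripotency genes.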

Other observations

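The test of imprinted genes in this part was chosen after the discordance of imprinted genes had been seen, and the genes here were named after their values were seen.

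Of 6569 CpG-rich gene ends, 12 were methylated, and 5 of them are given here as single values. D1Pas1, a testis RNA helicase gene, stood at 94.3% (262 calls) and Dazl at 97.9%. Apobec3, an antiviral cytidine deaminase gene, stood at 96.9% in 324 calls on chromosome 15 from 79917719 to 79919218. Grin3b, a glutamate receptor gene, stood at 96.3% (624 calls) and Polrmt, the mitochondrial RNA polymerase gene, at 84.7% (1140 calls). Whether these windows are the starts of the genes is unknown without strand.

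Of the 427 discordant gene ends, 23 were discordant in none of the 20 shuffles. No single shuffle was set against the others in the same way. How many such ends would arise without differences between cells is therefore unknown. The 23 ends include Plagl1 (61.5% of 13 cells at 80% or more, 30.8% at 20% or less) and Gnas (64.7% and 29.4% of 17 cells) of the imprinted list, and Cdkn1c, an imprinted cell cycle inhibitor gene of the stem cell list (21.7% and 60.9% of 23 cells). The end with the highest smaller share was that of Tmem267, on chromosome 13 from 119487086 to 119488585, with 51.9% and 33.3% of 27 cells. The neighbouring Hoxa5 and Hoxa6 ends, whose windows overlap, had 27.3% of 11 and 25% of 12 cells at 80% or more.

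A hypothesis is that such ends may reflect imprinted alleles, of which a sparse library often shows 1. Among intermediate gene ends with at least 10 cells that have 3 or more covered sites, 2 of 9 members of the imprinted list belonged to these 23, against 16 of 613 gene ends outside the list (2.61%), Cdkn1c among the 16. Random lists of 9 from outside the list held 0 at the median, and 0 to 1 in the middle 95%. The result rests on 2 genes and leaves the other ends unexplained, some of which may have arisen by chance.

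In 3 of the cells used, 0.0157% to 0.0196% of sites lay on chromosome Y and 2.76% to 3.12% on X. In the other 43 cells these shares were 0.0712% to 0.187% and 0.720% to 2.69%. The ends of the X range belong to the unevenly covered cells 53 and 52, and without cells 45, 52 and 53 it was 1.19% to 1.92%. The labels do not give the sex of the pooled mice. A window on chromosome 2 from 98660000 to 98669999, in no annotated gene, held 0.532% of all calls, and its share ranged from 0.174% to 1.19% between cells.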
